A study of Perkinsus olseni with 16 samples.

How the data were processed

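Total RNA of Perkinsus olseni trophozoites in 4 groups (a control pool in filtered seawater, and 1, 8 and 24 h with Manila clam plasma) had been labelled with Cy3 from 50 ng of RNA and hybridised to custom Agilent single-colour arrays, 4 arrays per group, per the labels. The deposited scanner files hold spot intensities from Agilent Feature Extraction 9.5, per the submitters' processing notes. Per the file headers, the processed intensity is the Cy3 brightness after background subtraction and detrending within an array, and no scaling between arrays is recorded; the mean and local background intensity of each spot and its flags are given beside it. The deposited series table also holds intensity values on a linear scale. From its values it was quantile normalized and left empty where a spot was not well above background: every column had the same maximum, its medians lay between 4105 and 4151, and its ranks were those of a scanner file (Spearman correlation of 1). How it was centred is not stated beyond that. In each plasma group its columns for replicates 3 and 4 held the ranks of the other one's scanner file, 6 columns in all, so it was used only as an alternative. That exchange is within groups. An exchange of the scanner files instead would make replicates 2 and 4 the repeats, and these differed by an SD of 0.489 at 1 h, 0.286 at 8 h and 0.187 at 24 h, more than replicates 2 and 3 (below) and clearly so at 1 h and 8 h.

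Each array held 15329 spots, of which 536 were controls and 14793 were probes of 55 to 60 bases, for 9939 contigs. Control spots were left out, and 30 spots with an outlier flag were set to missing. The processed intensity was taken to log2, with no pseudocount, and the 75th percentile over the probe spots of each array was subtracted. Spots with an identical sequence (842 sequences were spotted more than once) were averaged to 13883 probe sequences. Identical spots on an array differed by a median SD of 0.0399 to 0.0729 log2 units. A sequence was tested if it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 11946.

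Titles number the arrays of a plasma group from 1 to 4, while the descriptions call replicates 2 and 3 of that numbering 2 and 2b. In each plasma group these were the closest pair, with an SD of log2 differences of 0.192 at 1 h, 0.133 at 8 h and 0.168 at 24 h, where the next closest pairs had 0.294, 0.239 and 0.187. In the control pool, where no repeat is described, the same numbers ranked 3 among the pairs. They were averaged and counted as 1 replicate, and replicate 2 below names that average. The consensus correlation within such pairs was 0.803. The arrays lay on 2 slides, with 2 arrays of every group per slide.

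One linear model over the 4 groups, with 4 control and 3 replicates per plasma time, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior). Each plasma time was compared with the control pool and with the other times, giving 6 comparisons, each with Benjamini-Hochberg adjustment over the sequences tested and a threshold of 0.05. The fit was tested on simulated data for the 1 h comparison, with 200 of 11946 sequences changed: it called 47.8% of those changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 12 of 11746 unchanged ones. The simulated noise was normal, with the same spread in all groups and no shift of whole arrays. In the real data the spread differed between groups (below), so these rates hold only under the assumptions of the fit. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as at least the ratio of the bright group's mean to the mean of, per array, the higher of the dimmest probe well above background and the probe's own signal. Such a bound holds for the processed intensity only, and the normexp alternative gave lower folds. Overlaps between comparisons that share the controls were set against 100 draws in which residuals of the 13 replicates were dealt anew to the groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

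Before the data were examined, the design, the alternatives and 28 lists of genes defined by patterns over gene names were fixed. All 14793 probes are described as unknown and have only their identifier as a name, and no table pairing probes with genes was used here, so no list could be applied and none of the 28 gives a result. For the same reason the rule for named genes was reduced to its part for unnamed probes: at most 2 that rose and 2 that fell per comparison, by the largest fold among those past the threshold with 1 probe per transcript component. Alternatives were the normexp background correction (offset 50), quantile and median scaling, the deposited series table, no filter or a filter on all arrays, outlier spots kept, repeats as separate arrays with and without an estimated correlation, a trended and robust prior, only the groups compared, the replicate number or the slide as a block, each replicate left out, and stricter thresholds. Scaling to 6 of the 10 E1A spike-in transcripts (those well above background on at least 50% of their spots on every array), the spike-relative signal as a covariate, each slide alone, the matched series table, another pair of repeats and every probe name separately were added after seeing the data.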

Results

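Gene expression was measured in trophozoites, the vegetative stage, of Perkinsus olseni, a protozoan parasite of clams, after contact in vitro with plasma of the Manila clam (Ruditapes philippinarum). The plasma, or filtered seawater in the controls, filled an insert of 2.5 mL that a membrane with 0.2 µm pores parted from the parasites in 2.5 mL of seawater. RNA of parasites kept with plasma for 1, 8 or 24 h and of a control pool was hybridised to 16 single-colour arrays, 4 per group. Per the labels' protocols controls were sampled at each of the 3 times, but the control arrays are described only as a pool with no time, so a difference from it can come from the plasma or from time in the well. Within each plasma group 1 pair of arrays was described as repeats of the same replicate and was averaged, which left 3 replicates per plasma time and 4 of the control pool. All replicates came from the same culture, so the p-values measure only the spread between these samples, which is partly technical. The design text calls the replicates pseudo-replicates. Whether the 4 control arrays are separate samples or repeats of 1 pool is not stated, so n = 4 may count technical repeats. Between 11344 and 13553 of the 14793 probe spots were well above background on an array, and 11946 probe sequences from 7903 transcript components entered the tests. The files pair no probe with a gene name, so probes are given by their identifiers, and the number of arrays limits the precision of every value.

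The groups separated on the first principal component of the log2 signals, which held 55.96% of the variance over 10566 probe sequences. Control replicates lay at -9.67 ± 0.912 (SD, n = 4). The 1 h replicates lay on one side of them, at -33.0 ± 13.1 (SD, n = 3), and the 24 h replicates on the other, at 36.9 ± 6.46 (SD, n = 3). The 8 h replicates lay between these, at 5.92 ± 9.44 (SD, n = 3). Control replicates varied least, with a median SD of 0.0798 log2 units over the tested probe sequences, against 0.256 at 1 h, 0.156 at 8 h and 0.135 at 24 h. The control value was little above the median SD between identical spots on an array (0.0399 to 0.0729). Replicate 4 of the 1 h group stood apart from the others of its group, at -18.1 on this component.

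**Figure D1:**
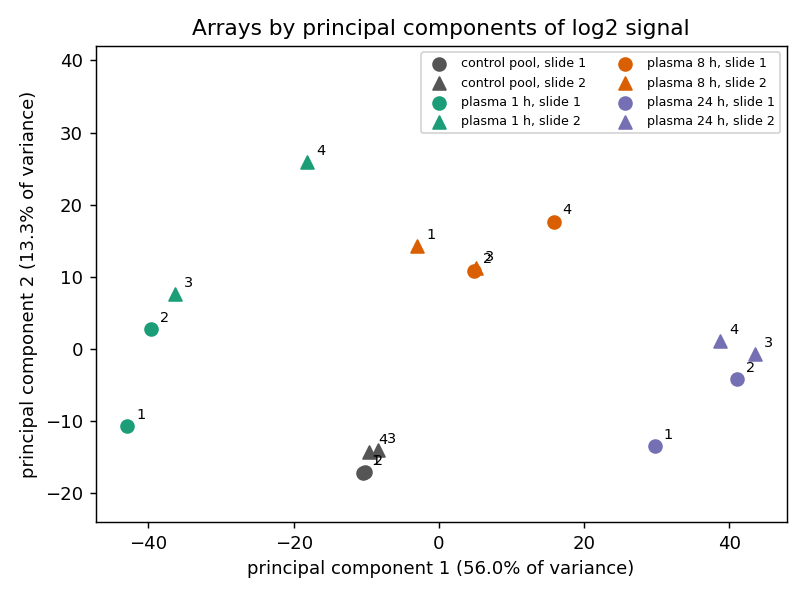
First and second principal components of the normalised log2 signal of the 16 arrays (axes in component units, with the percentage of variance), coloured by group and with the slide as the marker; numbers are replicates. The 1 h arrays lie at the left, from -42.9 to -18.1, and the 24 h arrays at the right, from 29.7 to 43.5, of the control arrays.

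The first comparison asked how parasites differed after 1 h with plasma from the control pool. In all, 2755 probe sequences changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), or 23.1% of those tested; 884 rose and 1871 fell. Most changes were small, with a median of 1.42-fold for rises and 1.45-fold for falls, but 136 sequences rose and 218 fell at least 2-fold, and 29 rose against 6 that fell at least 4-fold. The 2-fold balance turned with the processing. It was 248 risen and 117 fallen with quantile normalization, 198 and 126 with median scaling, and 66 and 60 with normexp. The largest measured rise was that of comp9686_c0_seq1_2, which was not well above background on any control array and was bright on every 1 h array. Its signal was at least 1401-fold above the control floor, with a measured log2 fold change of 11.92 ± 0.41 (SE; adjusted p = 5.45e-08, limma); with normexp background correction, which shrinks folds near background, the change was 8.69, or 414-fold. Another probe of the same contig, of the other orientation, was comp9686_c0_seq1reverse_1, also not well above background on any control array. Its measured log2 fold changes were smaller, at 5.39 at 1 h, 2.00 at 8 h and 5.36 at 24 h. The probe comp7619_c0_seq1reverse_1 was measured on all control arrays and rose by 7.73 ± 0.30 log2 units, or 213-fold (adjusted p = 7.00e-08, limma). Contig268reverse_1 (probe sequence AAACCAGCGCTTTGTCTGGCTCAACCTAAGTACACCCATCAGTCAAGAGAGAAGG) fell by 2.88 ± 0.28 log2 units, or 7.35-fold, the largest measured fall (adjusted p = 4.48e-05, limma); without control replicate 1, whose signal stood above the other controls, it fell by 2.57, and with normexp its change was -1.95. The dim probe comp8439_c0_seq3_1 was well above background on 2 of the 4 control arrays and on no 1 h array. It fell by 2.72 ± 0.68 log2 units, at least 4.08-fold with all 4 controls (adjusted p = 0.0144, limma), and fell by 1.87 without that control replicate. This fall missed the threshold in 4 of 31 alternative settings, with a change of -0.61 under normexp background correction. Rises made up 32.1% of the changes with arrays scaled to the 75th percentile, 46.2% with quantile normalization, 64.0% with arrays scaled to the median and 76.9% in the deposited series table, so the balance of directions is not settled. Under each of the 75th percentile, quantile and median scalings, 795 sequences rose and 939 fell. Without 1 h replicate 4 the count was 4452, and with fewer arrays it was 1939 on slide 1 and 1128 on slide 2.

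After 8 h with plasma 1895 probe sequences differed from the control pool, of which 990 rose and 905 fell. Of these, 150 rose and 36 fell at least 2-fold, and 27 rose and none fell at least 4-fold (limma at adjusted p under 0.05). The 2-fold counts were 203 and 41 with quantile normalization, 132 and 48 with median scaling and 64 and 13 with normexp. The probe comp4594_c0_seq1reverse_1 rose from a signal that was not well above background on any control array. It was at least 85.2-fold above the control floor at 8 h, with a measured log2 fold change of 8.15 ± 0.35 (SE; adjusted p = 2.34e-07, limma), and it had also risen at 1 h, by 7.10 ± 0.35, and at 24 h, by 6.13 ± 0.35 log2 units. With normexp its change at 8 h was 5.04, or 33.0-fold, below that bound. The probe comp64176_c0_seq1_1, well above background on 1 of the 4 control arrays, rose by 7.23 ± 0.82 log2 units (adjusted p = 0.00027, limma), and 5.24 with normexp. Among the falls, comp11584_c0_seq1reverse_1 (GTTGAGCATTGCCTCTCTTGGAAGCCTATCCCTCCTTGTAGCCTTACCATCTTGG) was lowered by a log2 fold change of -1.91 ± 0.12 (adjusted p = 3.86e-06, limma). With normexp it was -1.41, and it missed the threshold in 1 of 34 alternative settings, the deposited series table (-1.19). This probe missed the threshold at 1 h (-0.36 ± 0.12, adjusted p = 0.052, limma) and rose at 24 h, by 1.31 ± 0.12. The dim probe comp273392_c0_seq1_1 fell by 1.78 ± 0.54 log2 units (adjusted p = 0.0444, limma) and fell by 1.16 without control replicate 1. This fall is not firm: it missed the threshold in 16 of 33 alternative settings, with a change of -0.63 under normexp background correction. Rises made up 52.2% of the 8 h changes and 85.9% of the 767 in the deposited series table, so their balance is not settled either. Of the 3 counts against the control pool, that at 8 h moved most when a replicate was left out: it was 1026, 1074 and 1230 without 8 h replicate 1, 2 or 4, 1040, 1128 and 1168 without control replicate 2, 3 or 4, and 3352 without 1 h replicate 4, which only enters the shared spread. The 8 h count was below that at 1 h in the main analysis, but above it with only the groups compared (3485 and 1868), with the spike-relative signal as a covariate (3791 and 1245), without 1 h replicate 1 (2699 and 2535) and in the matched series table (316 and 308); slide 1 alone gave 325 and slide 2 alone 437.

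After 24 h with plasma 4757 probe sequences (39.8%) differed from the control pool, the largest of the 3 counts except with arrays scaled to spike-in transcripts, where the 1 h count was the largest. Of these, 2409 rose and 2348 fell, 577 rose and 274 fell at least 2-fold, and 127 rose against 13 that fell at least 4-fold (limma at adjusted p under 0.05). The 2-fold counts were 614 and 284 with quantile normalization, 449 and 431 with median scaling and 321 and 102 with normexp. The probe comp9686_c0_seq1_2 was again the largest measured rise, at least 869-fold above the control floor (log2 fold change 11.23 ± 0.41, adjusted p = 1.33e-08, limma), and comp4594_c0_seq1reverse_1 was at least 21.0-fold above it (6.13 ± 0.35, adjusted p = 2.84e-07, limma). With normexp these changes were 7.98 and 3.15, or 253-fold and 8.85-fold, below those bounds. The probe comp640397_c0_seq1reverse_1 (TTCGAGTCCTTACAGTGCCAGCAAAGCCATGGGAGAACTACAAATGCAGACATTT) fell by 2.57 ± 0.47 log2 units, the largest measured fall (adjusted p = 0.00136, limma). With normexp its change was -1.09, and it missed the threshold in 2 of 33 alternative settings, both with the deposited series table (-1.22). The same probe was at -0.42 ± 0.47 at 1 h (adjusted p = 0.563, limma) and had fallen by 1.61 ± 0.47 at 8 h. The probe comp407931_c0_seq1_1 fell by 2.44 ± 0.56 log2 units (adjusted p = 0.00527, limma) and fell by 1.84 without control replicate 1. It was well above background on 1 control array and 1 of the 24 h arrays, and it missed the threshold in 3 of 33 alternative settings, with a change of -0.63 under normexp background correction. Rises made up 50.6% of the changes with the 75th percentile, 47.7% with quantile normalization, 34.7% with median scaling and 70.1% in the deposited series table. Under each of the 75th percentile, quantile and median scalings, 1721 sequences rose and 2127 fell. The count was 2944 on slide 1 and 3703 on slide 2.

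**Figure D2:**
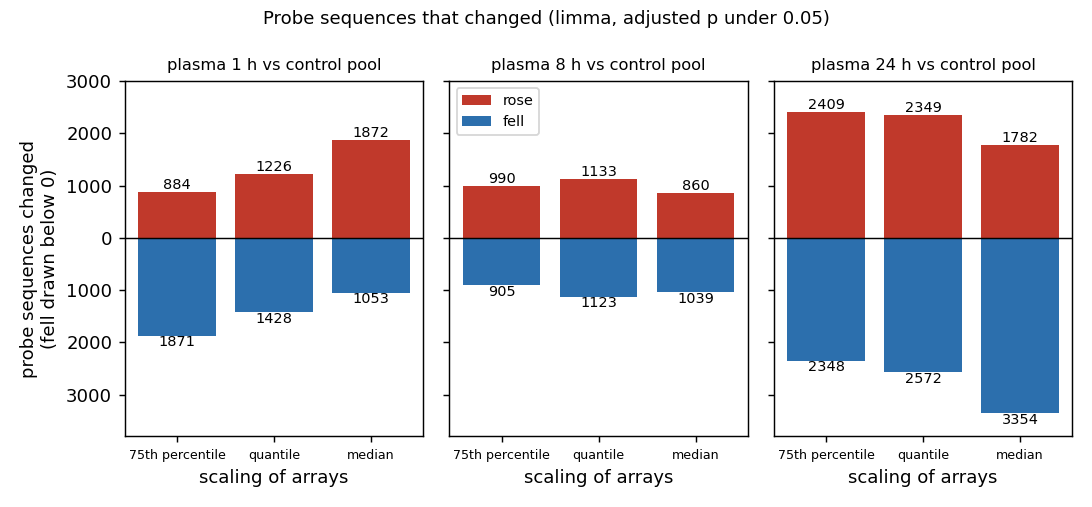
Probe sequences that rose (above 0) or fell (below 0) against the control pool at each time (limma, adjusted p under 0.05), with arrays scaled to the 75th percentile, by quantile normalization or to the median. At 1 h the balance turns from 884 risen and 1871 fallen to 1872 risen and 1053 fallen with the scaling, while the total of risen and fallen sequences is largest at 24 h under each of these scalings.

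The comparisons between plasma times asked how the response moved on from 1 h to 24 h. From 1 h to 8 h, 2950 probe sequences changed, 1850 upwards and 1100 downwards; from 8 h to 24 h, 2905 changed, 1672 upwards and 1233 downwards. Between 1 h and 24 h, 6134 changed (limma at adjusted p under 0.05), 3327 upwards and 2807 downwards. The probe comp9686_c0_seq1_2 fell by 5.21 ± 0.44 log2 units from 1 h to 8 h (adjusted p = 1.00e-05, limma) and rose again by 4.52 ± 0.44 from 8 h to 24 h (adjusted p = 3.05e-05, limma). The probe comp7619_c0_seq1reverse_1 fell by 3.72 ± 0.32 from 8 h to 24 h (adjusted p = 1.45e-05, limma). From 1 h to 8 h the largest measured rise, 3.82 ± 0.24 log2 units, was in comp18423_c0_seq1_2 (adjusted p = 1.50e-06, limma), which stayed high at 24 h. Between 1 h and 24 h the largest measured changes were a rise of Contig1397_2 by 5.84 ± 0.29 (adjusted p = 3.99e-08, limma) and a fall of comp8431_c0_seq2reverse_1 by 6.08 ± 0.44 log2 units (adjusted p = 7.73e-07, limma). The latter was well above background on 2 of the 4 arrays at 24 h; with normexp these changes were 4.11 and -3.43, and that of comp18423_c0_seq1_2 was 2.88. With median scaling the share of rises went from 62.7% to 26.1% for 8 h against 1 h, from 57.6% to 43.8% for 24 h against 8 h and from 54.2% to 30.0% for 24 h against 1 h; with quantile normalization the 8 h against 1 h share was 48.2%. In the deposited series table the shares were 49.7%, 47.2% and 50.1%, and 66.4%, 66.7% and 57.6% with its columns matched to the scanner files. The 8 h against 1 h count was 6032 without 1 h replicate 4 and 1785 without 8 h replicate 4.

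Grouped by their course over the 3 times, 5522 sequences did not pass the test at any time. The group called at 24 h but at neither earlier time held 1060 sequences that rose and 1532 that fell; 898 and 1199 of these also differed in that direction between 24 h and 1 h. The group called at 1 h and at no later time held 458 that rose and 624 that fell, of which 382 and 512 had moved back by 24 h in the test of 24 h against 1 h. Both groups were chosen by the same values, which favours these directions, so the counts for 24 h against 1 h are no separate support. Changes at 8 h and 24 h overlapped, with 721 sequences risen at both times and 483 fallen at both. Independent lists of those sizes would share 200 and 178; simulated groups with no effect, which share the controls, shared 0 in 100 draws, which gives no baseline for lists with real effects. With the controls split 2 and 2, so that the times shared none, 240 to 337 sequences rose and 127 to 163 fell at both times, and 25 to 41 had opposite calls. The overlap that independent lists would give with split controls was not computed, so 200 and 178 are no baseline for these counts. The fold changes at 8 h and 24 h had a correlation across probes of 0.63, inside the range of the simulated groups (-0.32 to 0.92, mean 0.46). Their covariance was 0.17, against a mean of 0.02 and a maximum of 0.09 in the simulated groups. The simulated controls took residuals of all groups, while the real controls varied least, so the simulated ranges overstate what shared controls give. Probes are not independent replicates.

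The changes at 1 h and 24 h often had opposite signs. In all, 712 sequences fell at 1 h and rose at 24 h, and 181 rose at 1 h and fell at 24 h, against 377 and 174 for independent lists; 165 rose and 330 fell at both times, against 178 and 368. The 712 sequences had a median log2 fold change of -0.58 at 1 h, 0.07 at 8 h and 0.64 at 24 h. The correlation of fold changes across probes was 0.03 and the covariance 0.01, both inside what simulated groups with no effect gave with the shared controls (correlations from -0.36 to 0.87, mean 0.45, and covariances with a mean of 0.02 and a maximum of 0.09). The simulated controls took residuals of all groups, while the real controls varied least. These ranges thus overstate what shared controls give, and lying inside them decides nothing. With the controls split 2 and 2 the correlation lay between -0.05 and -0.02, and 440 to 499 sequences had opposite calls. In these splits 65 to 79 sequences rose and 142 to 150 fell at both times. The opposite group held 781 sequences with quantile normalization and 989 with median scaling, and 374 against 340 of the same direction with the spike-relative signal as a covariate. Its members changed with the scaling. Of the 893 in the main analysis, 580 kept both directions with quantile normalization and 550 with median scaling. A further 270 sequences changed in the same direction at all 3 times, 100 upwards and 170 downwards.

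**Figure D3:**
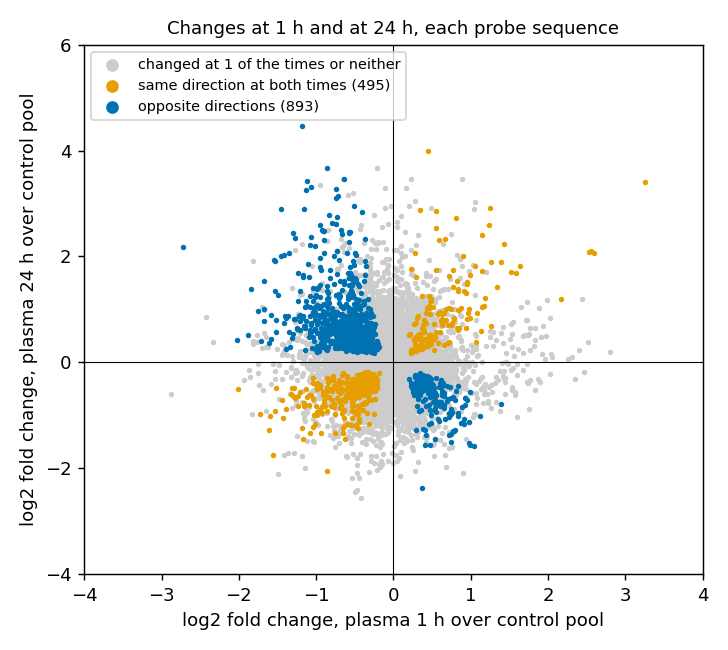
Log2 fold change against the control pool at 1 h (horizontal axis) and 24 h (vertical axis) of each tested probe sequence; 12 sequences lie outside the axes. The 893 sequences changed in opposite directions (blue) outnumber the 495 changed in the same direction (orange).

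A set of 38 probe sequences was not well above background on any control array and rose with plasma at least 4-fold in the fitted values at 1 time or more. Of these, 17 had risen at 1 h, with a median measured log2 fold change of 5.11 at 1 h, 2.69 at 8 h and 2.06 at 24 h; 9 of them fell between 1 h and 24 h, 3 rose and 5 did not pass that test. The other 21 had not risen at 1 h (median -0.58) and were risen at 24 h, with a median of 2.64. This set was chosen after the values were seen, and its measured folds are against signals near background. Its choice and its division by the 1 h call used these same values. That favours a later decline in the 17 and requires a later rise in the 21, so these courses are no separate support.

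**Figure D4:**
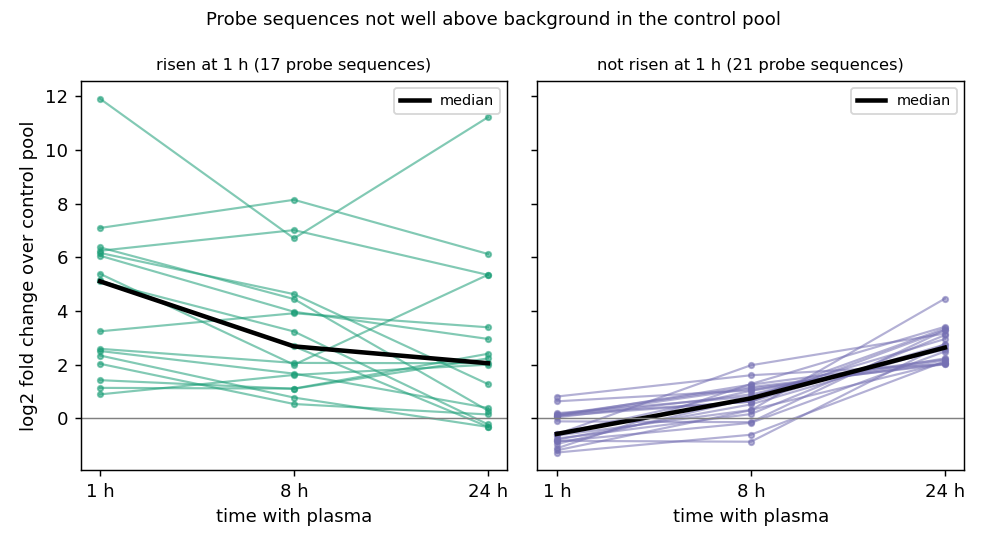
Measured log2 fold change over the control pool at 1, 8 and 24 h (points joined by lines, 1 line per probe sequence, median in black) of the 38 probe sequences that were not well above background in the control pool. Those risen at 1 h start at a median of 5.11 and end at 2.06, and the others go from -0.58 to 2.64. The choice of the set and its division by the 1 h call favour these courses.

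Fold changes were also compared between different probes of the same contig. Among 3031 contigs with 2 tested probes of the same orientation, log2 fold changes had a correlation across contigs of 0.79 at 1 h, 0.75 at 8 h and 0.79 at 24 h. Both probes changed in the same direction in 467 of the 994 contigs with any change at 1 h, 294 of 664 at 8 h and 895 of 1465 at 24 h, and in opposite directions in 2, 0 and 17.

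All of these values are relative to the bulk of the probes on an array. Relative to the E1A spike-in transcripts, the 75th percentile of the probe signal was lower with plasma than in the control pool, where it lay at 1.32 ± 0.116 (SD, n = 4, log2). It was 0.14 ± 0.536 at 1 h, 0.44 ± 0.716 at 8 h and 0.43 ± 0.348 at 24 h (SD, n = 3 each). These are differences of -1.18, -0.88 and -0.90, each with an exact two-sided permutation p of 0.0286, the smallest that 35 splits allow (with Benjamini-Hochberg adjustment over the 3 tests the value stays 0.0286). The 3 tests share the same 4 controls, which may be repeats of 1 pool, so their results are not independent. Whether the spike-ins were added in the same amount to every labelling is not given in the sources used here, and these differences and the spike-scaled counts rest on that. On slide 1 the differences were -1.46, -0.41 and -0.84, and on slide 2 they were -1.11, -1.10 and -0.79. With arrays scaled to the spike-ins, the median of all probes was -1.23, -0.91 and -0.92 log2 units against the control pool, and nearly all calls were falls (10867 of 10900 at 1 h, 6810 of 6851 at 8 h and 6570 of 6735 at 24 h).

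**Figure D5:**
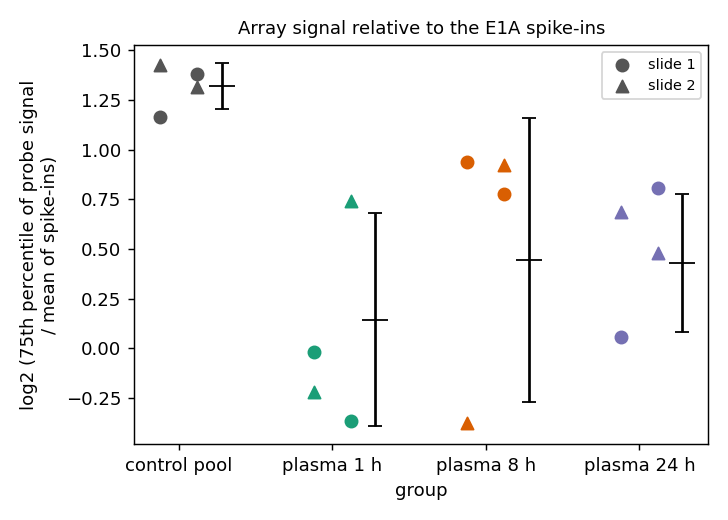
Log2 ratio of the 75th percentile of probe signal to the mean of the E1A spike-ins (vertical axis) for each array by group, with the slide as the marker; bars give the mean and SD over 4 control replicates or 3 replicates per plasma time. The control arrays lie between 1.16 and 1.43, above every plasma array.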

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

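All tests of explanations in this part were chosen after the results were seen.

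Expression with plasma differed between times by the tests of the differences themselves, which hold time in the well as well as plasma: 2950 probe sequences between 8 h and 1 h, 2905 between 24 h and 8 h and 6134 between 24 h and 1 h. Among the named rises, comp9686_c0_seq1_2 had a log2 difference of -5.21 at 8 h against 1 h and of 4.52 at 24 h against 8 h. For comp7619_c0_seq1reverse_1 the differences were -1.25 for 8 h against 1 h, -3.72 for 24 h against 8 h and -4.97 for 24 h against 1 h. For comp4594_c0_seq1reverse_1 they were -2.02 for 24 h against 8 h and -0.97 for 24 h against 1 h, and for comp64176_c0_seq1_1 the difference was -2.89 for 24 h against 8 h.

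Of the 35 splits of the control and plasma replicates, 1, the real one, gave as many changed sequences at each time, a share under 0.05. At 1 h it gave 2755 against at most 14 in other splits. At 8 h these counts were 1895 and 39, and at 24 h 4757 and 220. The other splits mix plasma and control replicates, which widens the spread and lowers their counts. All replicates came from the same culture, so a difference in handling between the groups is not excluded by the splits. Between plasma times there are 10 splits, too few for a share under 0.05; the real split gave 2950 against at most 2053 for 8 h and 1 h, 2905 against 0 for 24 h and 8 h, and 6134 against 1378 for 24 h and 1 h. The split with 2053 exchanged 1 h replicate 4 for 8 h replicate 1, which points to a structure of the samples: these were the highest 1 h array (0.74) and the lowest 8 h array (-0.38) in signal relative to the spike-ins. The latter stood far from the other 8 h arrays, with a gap of 0.878 of the group's range.

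Named falls often had 1 control array far from the others. The gap was 0.905 of the control range for Contig268reverse_1, 0.918 for comp8439_c0_seq3_1, 0.893 for comp273392_c0_seq1_1 and 0.872 for comp407931_c0_seq1_1, and in each it was control replicate 1 that was high; chance gives such a gap in about 1 of 20 unselected groups, and probes named for large falls were selected in a way that favours a high control. Across the array, 316 sequences were at least 2-fold above the other 3 controls in control replicate 1, against 19 to 23 for each other control. Of these, 46.8% lay in the last 25% of the array's lines of spots, where 21.1% of other dim sequences lay (Fisher's exact test, p = 1.25e-20), so a local fault on this array may have raised them. RNA of plasma-exposed cells in that sample is argued against, since these sequences had a median log2 level of only 0.35 at 24 h over control replicates 2 to 4, where control replicate 1 had 1.96; other causes stay open. Only 14, 5 and 26 of the 316 were among the sequences that fell at 1, 8 and 24 h.

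The 893 sequences with opposite changes at 1 h and 24 h cannot be read as plasma responses in both directions without knowing the control pool. The protocol has controls taken at each time, so it may be a mixture of them; a drift of expression in the wells with no plasma effect would then leave it between 1 h and 24 h, which all 893 allow, so plasma and time cannot be told apart for them. Without error such a mixture would give none of the 270 sequences changed in the same direction at all 3 times. An error in the shared control mean moves all 3 comparisons the same way, however, and the number this would give was not computed. The 270 therefore do not decide on that account, and an array-wide technical difference between plasma and control arrays remains open for them. One aberrant 1 h replicate is argued against as the whole cause of the opposite changes, since 789, 636 and 1626 sequences were opposite without replicate 1, 2 or 4. The spike-relative signal stays open: with it as a covariate 312 of the 893 kept both directions and opposite calls (374) hardly outnumbered those of the same direction (340), in a fit where it is partly confounded with the groups.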

How the results depend on the processing

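The spike-in settings, each slide alone, the matched series table and the other pair of repeats were chosen after the data were seen. The alternatives not named here kept all 6 counts within 1.5 times, and no named probe reversed in 784 alternative values, of which 26 missed the threshold; all 26 belonged to falls against the control pool, 16 of them to comp273392_c0_seq1_1. Comparisons are given in the order 1 h, 8 h and 24 h against the control pool, then 8 h against 1 h, 24 h against 8 h and 24 h against 1 h, and the cause was not tested unless stated. The deposited series table gave 1220, 767, 2934, 640, 1170 and 3856 changed sequences, and 308, 316, 2772, 229, 858 and 3213 with its columns matched to the scanner files, (64.3%, 77.5% and 74.9% of them rises against the control pool), where the median residual SD was 0.261 against 0.183. Repeats as separate arrays, which adds samples, gave 3008 at 8 h and 5300 for 8 h against 1 h. Only the groups compared gave 3485 at 8 h and 867 for 8 h against 1 h. Averaging replicates 2 and 4 as the repeats, against which the distances between arrays speak, gave 4697 at 1 h, 3262 at 8 h, 5503 for 8 h against 1 h and 4410 for 24 h against 8 h. Spike-in scaling gave 10900 at 1 h, 6851 at 8 h, 352 for 8 h against 1 h, 159 for 24 h against 8 h and 1588 for 24 h against 1 h, and the spike-relative signal as a covariate gave 1245 at 1 h and 3791 at 8 h. The slide as a block gave 2736, 1974, 4890, 2979, 2960 and 6218. With fewer samples, slide 1 alone gave 1939, 325, 2944, 5233, 1735 and 5830, and slide 2 alone gave 1128, 437, 3703, 1105, 2055 and 4984. An adjusted p under 0.01 left 1325, 642 and 2967 against the control pool, and a 2-fold minimum left 354, 186 and 851. Leaving out each replicate gave 1843 to 4452 at 1 h, 1026 to 3352 at 8 h, 3383 to 5860 at 24 h, 1785 to 6032 for 8 h against 1 h, 2016 to 3946 for 24 h against 8 h and 4888 to 7377 for 24 h against 1 h; beyond 1.5 times these were 1 h replicate 4 (highest values), 8 h replicates 1, 2 and 4 and control replicates 2, 3 and 4. Whether the replicate numbers pair the samples is not settled. Same-numbered arrays of different groups had correlated deviations over 0.1 in 12 of 24 pairs (range -0.15 to 0.68). Of the 24 pairs, 7 correlated best with their own number. Number 1 had 0.68 between 1 h and 24 h and number 4 had 0.56 between 1 h and 8 h, but number 2 had -0.14 between 1 h and 24 h. The title number as a block with 4 separate arrays gave 4575, 3552, 6367, 5950, 4730 and 7873, and the description number as a block gave 2508, 1715, 4652, 3733, 3049 and 6482. Median scaling shifted the median of all sequences by 0.15 at 1 h, -0.12 at 24 h, -0.20 for 8 h against 1 h and -0.27 for 24 h against 1 h, and the changes are relative to such a shift; no sequence was called in opposite directions under the 75th percentile, quantile and median scalings except 15 for 24 h against 1 h. The camera tests of the 28 gene lists were not run, since the files name no genes. Fold changes of probes near background are bounds or depend on the background correction.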

Other observations

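The tests in this part were chosen after the results were seen.

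The 38 sequences that were dark in the control pool and rose with plasma followed different courses, and 1 hypothesis is that some report RNA that came with the plasma. For the 21 that had not risen at 1 h this was not tested and stays open. For the 17 risen at 1 h, RNA of 1 source in fixed proportions is argued against: their changes from 1 h to 24 h had an SD of 2.40 log2 units across sequences, where the median standard error of one was 0.44. A signal near background limits how far a dim sequence can fall, which adds to that SD. Even so, 9 of the 17, which came from 15 transcript components, fell and 3 rose between these times. Choosing sequences by their rise at 1 h favours such falls. A transient change of parasite transcripts and the unequal decay of RNA that came with the plasma both remain open, since their median change from 1 h to 24 h, -0.97, could come from either, and the files give no gene names to separate them.

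Probes against the start of messenger RNAs were looked at by orientation. Perkinsus and dinoflagellate messenger RNAs carry a short spliced leader at their start, which ends in TTGGCTCAAG. Of 83 probe sequences that hold its reverse complement, CTTGAGCCAA, 11 (13.3%) were well above background on all 16 arrays, against 76.6% of the 13798 sequences with neither (Fisher's exact test, p = 5.84e-34); only 2 sequences hold the leader end as in the messenger RNA, and 1 of these was well above background on all arrays. The comparison of the 83 does not separate orientation from position along the transcript, since the leader end marks the start of a transcript. Of 732 contigs with probes of both orientations, 593 kept both after identical sequences were merged under 1 name. In 69 of these 593 contigs one orientation was above background on all arrays and the other on none, and in 164 both were above background on all arrays.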
